A study of Mus musculus with 18 samples.

How the data were processed

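RNA sequencing of the choroid plexus, the epithelial and vascular tissue of the brain ventricles that makes cerebrospinal fluid, was available for 18 libraries of 2 related mouse strains at 12 and 16 weeks of age. MRL/lpr mice carry the lpr allele of Fas and develop a lupus-like autoimmune disease, and MRL/+ mice are the control strain with the intact gene. Each strain and age formed a group of its own: MRL/lpr at 12 weeks (6 libraries), MRL/lpr at 16 weeks (6), MRL/+ at 12 weeks (3) and MRL/+ at 16 weeks (3). The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these samples.

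The deposited table holds raw counts of reads per gene, 1 column per library, for 50584 genes with their chromosome, start, end and strand. Per the submitters' processing notes, the reads were aligned with STAR 2.5.3a to the mouse genome GRCm38, counted over exons with featureCounts 1.26.0 and analysed with DESeq2 1.16.1. The annotation release, the treatment of reads that align to several places and the strand setting of the counting are not given in the sources used here. These settings matter for near-identical genes, such as the immunoglobulin heavy and lambda chain constant regions, Trbc1 and Trbc2, Hspa1a and Hspa1b, and the H2 genes, and for genes that overlap a neighbour. All values in the table were whole numbers, and total counts ran from 11164284 to 14602253 per library. A comparison of the 36 pairs of libraries within groups found none that held the same library: the smallest chi-square per gene of a pair was 6.10, where repeated sequencing of 1 library would give about 1.

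The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 16598 genes. Library sizes were scaled with TMM, a trimmed mean of log ratios, and a negative binomial model with 1 mean per group was fitted to all 18 libraries with the robust quasi-likelihood method. Tests of 5 contrasts were made per gene: MRL/lpr against MRL/+ at 12 weeks and at 16 weeks, 16 against 12 weeks within each strain, and the strain by age interaction. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Group levels are means of CPM with TMM-scaled library sizes, ± SD. Log2 fold changes carry the standard error (SE) of the fit. Where every control library was at 0, the fold is a lower bound against a floor of 3 counts over the pooled control group. Where the pooled control group held 1 to 3 counts, the fold is a ratio of counts with its exact 95% interval. These intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

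The comparisons, the tests, 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold markers of tertiary lymphoid structure chemokines, lymphoid organisation, B cells, plasma cells, immunoglobulin constant regions, germinal centre and follicular helper T cells, follicular dendritic cells, T cells, cytotoxic and natural killer cells, macrophages, dendritic cells, neutrophils, MHC class II and class I presentation, the type I interferon and interferon gamma responses, complement, cytokines, leukocyte adhesion, proliferation, choroid plexus epithelium, epithelial junctions, endothelium, fibroblasts and extracellular matrix, lymphatic vessels, ependyma and cilia, neurons, astrocytes, oligodendrocytes, microglia, erythrocytes, immediate early genes, and heat shock and RNA stress. The 32 lists with at least 5 measured genes were tested with camera on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The erythrocyte list had 4 measured genes and was not tested. Camera compares a list with all other genes. It was repeated with the correlation estimated from the data, and fry tested whether the genes of a list moved on balance in 1 direction. The genes named in the text are Fas and a panel of 20 others. To these were added the 8 highest and 8 lowest fold changes of each strain comparison among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out gene models without a name and receptor gene segments. The 5 highest and 5 lowest of each age comparison and of the interaction were added in the same way, without the overlap condition for the interaction, and up to 4 members of each list with the smallest p. A list score per library is the mean over the list's genes of log2 CPM centred on the mean of all libraries. Scores were compared with exact two-sided permutation tests, in which 6 against 3 libraries make 84 splits and the smallest possible p is 0.0119. Correlations within the 6 MRL/lpr libraries of an age used exact permutation of the pairings.

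The fit was tested on simulated counts with the same depths, dispersions and group sizes, in which 50 of 16598 genes were changed at each fold. At 12 weeks the strain comparison recovered 14% of 1.5-fold, 44% of 2-fold, 78% of 4-fold and 92% of 16-fold changes, with 2 false calls. At 16 weeks it recovered 12%, 34%, 74% and 98%, with 4 false calls. The age comparison in MRL/lpr recovered 30%, 50%, 82% and 100%, with 6 false calls, and that in MRL/+ 2%, 30%, 74% and 82%, with 4 false calls. The interaction recovered 2%, 18%, 56% and 80%, with 1 false call. Of 30 simulated lists without a change, 0 were called by camera in each comparison, and the raised and the lowered list were called in all 5 comparisons. The simulated genes varied independently of each other. These lists therefore do not show how often camera wrongly calls lists of genes that vary together.

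The alternatives tried were RLE size factors in place of TMM, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter on low counts, a filter of at least 1 CPM in at least 6 libraries, a fit of only the compared groups, the replicate number as a block, a fold threshold of 1.5, fry or an estimated correlation for the lists, a median in place of a mean for the list scores, and leaving out each library in turn. Chosen after seeing the data were the neuron list score as a covariate, a scaling that gives the choroid plexus epithelium list the same mean in every library, and a fit without the 4 libraries with the highest sums of pineal gland, cerebellum or skeletal muscle genes. A fit with a leukocyte score, the mean of the T cell, B cell and macrophage list scores, as a covariate was also chosen after seeing the data, as were the lists of pineal gland, pituitary, skeletal muscle, cerebellum and clock genes. No library was left out of the main values. Plots were drawn with matplotlib 3.10.9.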

Results

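RNA was sequenced from the choroid plexus of MRL/lpr mice, a strain that develops lupus-like autoimmunity, and of MRL/+ control mice, at 12 and 16 weeks of age. The study concerns lymphoid tissue that forms in the choroid plexus of the lupus-prone strain, so the comparisons ask which genes differ between the strains at each age, and which change between the ages within a strain. There were 6 MRL/lpr and 3 MRL/+ libraries per age. Total counts per library ran from 11164284 to 14602253. Transcripts of Ttr (chromosome 18, 20665250 to 20674324), the thyroid hormone carrier made in bulk by choroid plexus epithelium, took 18.2 ± 1.79% and 15.9 ± 2.17% of the counts in MRL/lpr at 12 and 16 weeks and 16.2 ± 1.11% and 18.4 ± 1.39% in MRL/+. Mitochondrial transcripts took 7.79 ± 1.88% and 7.48 ± 2.0% in MRL/lpr and 7.44 ± 2.13% and 9.87 ± 0.914% in MRL/+. Gene positions are on GRCm38, and levels are CPM, mean ± SD, n = 6 for MRL/lpr and n = 3 for MRL/+.

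Fas (chromosome 19, 34290659 to 34327770), the death receptor gene that carries the lpr insertion, was counted over all of its exons, which does not separate transcripts that end at the insertion from whole ones, so its level is no check of the strain labels. The MRL/lpr libraries of 12 weeks, from replicate 1 to replicate 6, held 61, 29, 28, 25, 16 and 67 counts, and those of 16 weeks 66, 51, 32, 57, 22 and 14. The MRL/+ libraries held 21, 14 and 20 counts at 12 weeks and 28, 25 and 23 at 16 weeks. Fas stood at 2.84 ± 1.58 CPM in MRL/lpr and 1.33 ± 0.236 in MRL/+ at 12 weeks (log2 fold change 1.09, SE 0.46, adjusted p 0.18), and at 3.01 ± 1.31 and 2.24 ± 0.353 at 16 weeks (0.43, SE 0.45, adjusted p 0.53). Neither difference passed the test.

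At 12 weeks the choroid plexus of MRL/lpr held transcripts of lymphoid tissue at far higher levels than MRL/+. Cxcl13 (chromosome 5, 95956951 to 95961068), the chemokine that draws B cells into follicles, rose 58.3-fold to 60.6 ± 35.5 CPM from 1.05 ± 0.357 (log2 fold change 5.87, SE 0.76, adjusted p 0.00065). Jchain (chromosome 5, 88519809 to 88527891), the joining chain of secreted IgM and IgA, rose 261-fold to 546 ± 189.9 from 2.12 ± 2.11 (8.03, SE 1.03, adjusted p 0.00065). Cd3g (chromosome 9, 44969572 to 44980431), a chain of the T cell receptor complex, rose 177-fold to 18.9 ± 12.7 from 0.0996 ± 0.0502 (7.47, SE 0.97, adjusted p 0.00065). H2-Aa (chromosome 17, 34282744 to 34287827), an MHC class II chain, rose 29.5-fold to 357 ± 255 from 12.1 ± 2.6 (4.88, SE 0.77, adjusted p 0.0024). In the other direction, Dmgdh (chromosome 13, 93674433 to 93752831), a mitochondrial enzyme of choline breakdown, was 7.27-fold lower, at 23.9 ± 2.3 CPM against 174 ± 19 (-2.86, SE 0.14, adjusted p 3.6e-09). Of 16598 genes tested, 832 were higher and 223 lower in MRL/lpr. The median log2 fold change was 3.74 among the higher genes and -0.54 among the lower.

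**Figure D1:**
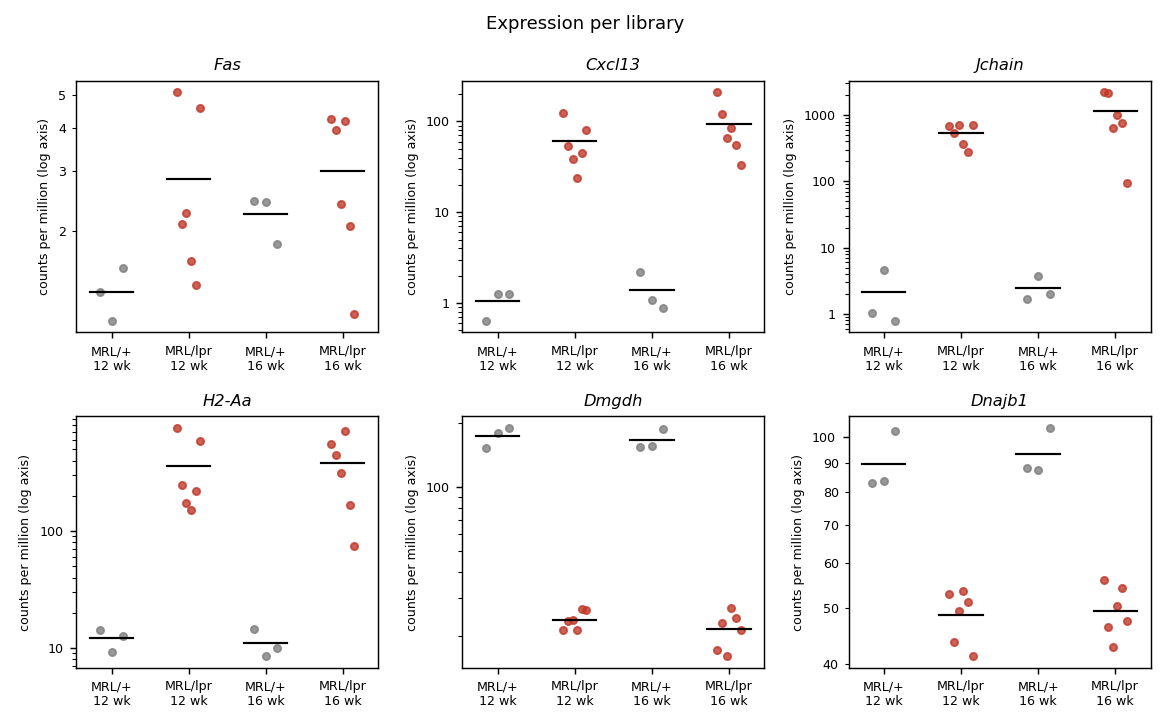
CPM (log axis) of 6 genes in each library, with MRL/+ in grey, MRL/lpr in red, 1 point per library and black lines at the group means. Every MRL/lpr library lies above every MRL/+ library of its age for Cxcl13, Jchain and H2-Aa and below for Dmgdh and Dnajb1, while the groups overlap for Fas.

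Among the genes named in advance for lymphoid tissue, Ltb (lymphotoxin beta, needed to form lymphoid tissue) rose to 20.9 ± 15.6 CPM from 0.263 ± 0.0918 at 12 weeks (log2 fold change 6.25, adjusted p 0.0027). Ms4a1, which codes for the B cell antigen CD20, was at 14.0 ± 9.27 CPM in MRL/lpr and had no counts in MRL/+, which makes it at least 193-fold higher (adjusted p 0.0030). Cd3e was at least 64.1-fold higher (adjusted p 0.0035). The T cell coreceptors Cd8a and Cd4 rose by a count ratio of 116 (95% counting interval 31.9 to 960.1, adjusted p 0.0029) and by 4.95 on the log2 scale (adjusted p 0.0048). Ighm rose by 5.31 on the log2 scale (adjusted p 0.012, and 0.0783, 0.0687 and 0.0705 without MRL/+ replicates 1, 2 and 3), or by 4.62 without MRL/lpr replicate 1. Igkc (chromosome 6, 70726435 to 70726966), the kappa light chain constant region, rose to 1807 ± 998 CPM from 5.96 ± 4.14 (304-fold, adjusted p 0.0016). The folds of Igkc and Jchain were 505 and 595 without MRL/+ replicate 2. Tnfsf13b, the B cell survival factor BAFF, rose 5.99-fold (adjusted p 0.017), with adjusted p 0.0979, 0.0546 and 0.103 without MRL/+ replicates 1, 2 and 3. The inhibitory receptor gene Pdcd1 rose by 5.16 on the log2 scale (adjusted p 0.0094), or by 4.57 with adjusted p 0.0671 without MRL/+ replicate 1, and with adjusted p 0.0519 without MRL/+ replicate 3. Cxcr5, the receptor of Cxcl13, passed with adjusted p 0.035, but not without MRL/lpr replicate 1 (0.0597) or without MRL/+ replicates 1, 2 or 3 (0.152, 0.104 and 0.147). Il21 rose 2.04-fold (adjusted p 0.037), but did not pass without MRL/lpr replicates 1 or 3 (0.0717 and 0.0509) or MRL/+ replicates 1 or 2 (0.188 and 0.155). The chemokine Ccl19 (count ratio 11.9, 3.91 to 59.3, adjusted p 0.073), the macrophage marker Cd68 (log2 fold change 2.01, adjusted p 0.071), the germinal centre regulator Bcl6 (-0.06, adjusted p 0.95) and Ttr (0.18, adjusted p 0.66) did not pass. Ccl21a had 0 counts in every library.

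Most lists of lymphoid genes were higher by camera at 12 weeks, but none of them with an estimated correlation. All gene lists below are given with the members that rose over all genes tested, the number adjusted over the list alone, and the median log2 fold change of the list. Of 10 tertiary lymphoid structure chemokines 8 rose (9 adjusted over the list alone, median 6.41), among them Ccl8 (chromosome 11, 82115185 to 82116799), which attracts T cells and monocytes, at 118 ± 80.8 CPM against 0.32 ± 0.204 (363-fold, adjusted p 0.00027), and Cxcl9, a T cell chemokine induced by interferon gamma (322-fold, adjusted p 0.00062, and 549-fold without MRL/+ replicate 2). Of 15 lymphoid organisation genes 10 rose (13 adjusted over the list alone, median 5.06, or 4.47 with 1 gene at its bound). Of 17 B cell genes 13 rose (15 adjusted over the list alone, median 5.86, or 5.83 with bounds). Of 12 plasma cell genes 9 rose (10 adjusted over the list alone, median 3.67). Of 12 immunoglobulin constant regions 10 rose (12 adjusted over the list alone, median 8.22, or 8.15 with bounds), with Igha at 499.8 ± 339 CPM against 1.71 ± 0.876 and Iglc2 202-fold higher (adjusted p 0.00012). Of 20 T cell genes 19 rose (20 adjusted over the list alone, median 6.13, or 5.93 with bounds), with Cd3d at least 159.7-fold higher (adjusted p 0.0016). Of 14 cytotoxic and natural killer genes 11 rose (12 adjusted over the list alone, median 5.20, or 4.96 with bounds), with Nkg7 rising 70.5-fold (adjusted p 0.0035). Camera called each of these 7 lists, with adjusted p 1.5e-16, 2.3e-12, 1.5e-15, 3.3e-11, 6.8e-20, 7.3e-29 and 6.8e-14 in this order, and each had adjusted p = 0.073 with an estimated correlation. Of 11 germinal centre and follicular helper T cell genes 8 rose (8 adjusted over the list alone, median 5.05, camera adjusted p 1.6e-07, adjusted p = 0.093 with an estimated correlation). Of 9 follicular dendritic cell genes 2 rose, Cxcl13 and the inhibitory Fc receptor Fcgr2b (3 adjusted over the list alone), and the list did not pass (median 0.10, camera adjusted p 0.056).

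Myeloid and antigen presentation genes were also higher at 12 weeks. Of 18 macrophage genes 12 rose (16 adjusted over the list alone, median 2.62), including the complement subunit C1qa at 176 ± 108 CPM against 15.9 ± 1.44 (11.1-fold, adjusted p 0.0027) and Lyz2, the lysozyme of phagocytes (28.7-fold, adjusted p 0.0027). Of 11 dendritic cell genes 6 rose (9 adjusted over the list alone, median 2.55), with Clec9a, a receptor of cross-presenting cells, up 12.0-fold (adjusted p 0.0032). Of 10 microglia genes 5 rose (6 adjusted over the list alone, median 1.13), with P2ry13 up 5.74-fold (adjusted p 0.0038). All 10 MHC class II genes rose (10 adjusted over the list alone, median 4.94), with the invariant chain Cd74 at 562 ± 432 CPM against 15.1 ± 5.27. Of 12 MHC class I genes 10 rose (12 adjusted over the list alone, median 2.95), with the immunoproteasome subunit Psmb8 up 25.6-fold (adjusted p 0.0030). Of 18 interferon gamma response genes 16 rose (17 adjusted over the list alone, median 4.61), with the GTPase Iigp1 at 207 ± 125 CPM against 1.85 ± 1.15. Of 15 complement genes 9 rose (14 adjusted over the list alone, median 3.03). Of 14 cytokines and inflammatory mediators 3 rose (10 adjusted over the list alone, median 1.35). Camera called these 8 lists with adjusted p 2.9e-17, 1.4e-08, 1.2e-07, 1.5e-14, 1.6e-13, 8.9e-21, 1.1e-12 and 3.0e-06 in this order, each with adjusted p = 0.073 with an estimated correlation. Of 23 type I interferon response genes 7 rose (17 adjusted over the list alone, median 2.96, camera adjusted p 1.5e-14, adjusted p = 0.114 with an estimated correlation), with the nucleic acid sensor Zbp1 up 97.8-fold (adjusted p 0.0024). Of 13 leukocyte adhesion genes 7 rose (12 adjusted over the list alone, median 2.67, camera adjusted p 2.1e-09, adjusted p = 0.090 with an estimated correlation). Of 18 proliferation genes 6 rose (16 adjusted over the list alone, median 1.82, camera adjusted p 3.3e-11, adjusted p = 0.093 with an estimated correlation). Of 6 neutrophil genes 2 rose (2 adjusted over the list alone, median 1.94, camera adjusted p 0.0067, adjusted p = 0.18 with an estimated correlation). The list holds 13 genes, of which 6 were measured, and the 2 were Lcn2 and Csf3r. Lcn2 did not pass in 2 and Csf3r in 6 of 9 fits without 1 library. Their adjusted p reached 0.0940 and 0.174, both without MRL/+ replicate 1.

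Few genes in the lists of the tissue's own cell types passed at 12 weeks. None of 23 choroid plexus epithelium genes passed (0 adjusted over the list alone), although the list was lower by camera (median -0.25, adjusted p 0.0046, adjusted p = 0.41 with an estimated correlation). None of 13 epithelial junction genes passed (0 adjusted over the list alone, median -0.23, camera adjusted p 0.0074, adjusted p = 0.29 with an estimated correlation). The fibroblast and extracellular matrix list was higher by camera (median 0.44, adjusted p 0.0062, adjusted p = 0.23 with an estimated correlation). Of its 14 genes 1 rose (1 adjusted over the list alone): the matrix proteoglycan Dcn, at 350.03 ± 57.0 CPM against 195 ± 56.5, with adjusted p 0.029. Dcn did not pass without MRL/lpr replicates 1 or 3 (0.0596 and 0.0509) or MRL/+ replicates 1, 2 or 3 (0.151, 0.0815 and 0.0513). No member passed over all genes, and camera called no list, among 14 endothelium genes (median 0.35, adjusted p 0.22), 5 lymphatic vessel genes (0.11, 0.67), 12 ependyma and cilia genes (0.63, 0.16), 14 neuron genes (-0.64, 0.28), 11 astrocyte genes (-0.17, 0.40), 13 oligodendrocyte genes (0.74, 0.13) and 12 immediate early genes (-0.40, 0.70). Adjusted over the list alone, 1 lymphatic vessel gene rose and 0 genes of the other 6 lists passed. The heat shock and RNA stress list was lower (median -0.46, camera adjusted p 5.9e-08, adjusted p = 0.073 with an estimated correlation), with 4 of 9 genes falling (7 adjusted over the list alone). They were the chaperones Hspa1b (chromosome 17, 34956436 to 34959238), 9.38-fold lower at 0.508 ± 0.173 CPM against 4.82 ± 2.72, Hspa1a (chromosome 17, 34969190 to 34972156, 4.02-fold), Dnajb1 (chromosome 8, 83608193 to 83612653, 1.84-fold) and Hsph1 (chromosome 5, 149614287 to 149636376, 1.78-fold), with adjusted p 0.00065, 0.0027, 0.00062 and 0.0027. Hspa1a and Hspa1b are near-identical, so reads may have been shared or lost between them.

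The ranking rule orders genes by the fitted fold, which has no firm value where the control counts are 0 or few, so its order is not that of the bounds and ratios printed here. At 12 weeks it took as highest Ly6d (chromosome 15, 74762056 to 74763620), a surface protein of early lymphocytes and epithelia, at least 280.2-fold higher at 20.5 ± 12.5 CPM (adjusted p 0.0021), Cd3d, Ms4a1 and Iglc3 (at least 87.0-fold, adjusted p 0.0030). It also took the MHC class I-like H2-M2 (count ratio 944, 169 to 37322, adjusted p 0.0016), the ubiquitin-like Ubd (chromosome 17, 37193892 to 37196095; count ratio 653, 181 to 5399, adjusted p 0.0062, and 0.0517 without MRL/+ replicate 1), Ighg2b (544-fold, adjusted p 0.0024, and 958-fold without MRL/+ replicate 2) and Iglc1 (count ratio 563, 192 to 2729, adjusted p 0.0021). The lowest were Dmgdh, the splicing regulator Esrp1 (6.67-fold lower, adjusted p 0.00027), the homeobox gene Tlx2 (5.95-fold, adjusted p 0.00062), the methyltransferase Bhmt2 (chromosome 13, 93655720 to 93674302; 14.4 ± 1.81 CPM against 55.0 ± 4.95, 3.82-fold, adjusted p 1.7e-05). They also held Scfd2 (3.27-fold, adjusted p 0.0012), Sowahb, the cation channel Mcoln3 (2.62-fold, adjusted p 0.0052) and Arhgap20. Sowahb (log2 fold change -1.53, adjusted p 0.016) and Arhgap20 (-1.28, adjusted p 0.013) stood at -0.71 and -0.83 without MRL/+ replicate 1, with adjusted p 0.296 and 0.172. Bhmt2 and Dmgdh lie side by side on chromosome 13. Counts of paralogs such as Iglc1 and Iglc3, or Ighg2b and the other heavy chain constant regions, may include each other's reads.

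The edgeR test called 1055 genes at 12 weeks (3560 at an unadjusted p under 0.05), and 263, 404 and 326 without MRL/+ replicates 1, 2 and 3. The split into higher and lower genes was 832 and 223 as scaled with TMM, and 991 and 21 when the libraries were scaled to the choroid plexus epithelium list. That scaling moved the median log2 fold change of all genes from -0.013 to 0.24. The 832 higher genes were 229, 336 and 283 without MRL/+ replicates 1, 2 and 3. The 223 lower genes were 118, 105, 508, 34, 68 and 43 without MRL/lpr replicates 1, 4 and 6 and MRL/+ replicates 1, 2 and 3. With voom and sample weights it was 1580 higher and 1910 lower, so the balance of the 2 directions depends on the method. Genes of other tissues were measured by marker lists written after the data were seen. Summed CPM of 8 pineal gland genes were 162 and 132 in MRL/lpr replicates 1 and 4 of 12 weeks and at most 57.9 elsewhere, and those of 8 skeletal muscle genes were 629 in MRL/+ replicate 1 of 16 weeks and at most 4.97 elsewhere. Those of 6 cerebellum genes were 363 in MRL/+ replicate 1 of 12 weeks against a median of 35.5, but also 197 in MRL/lpr replicate 2 of 12 weeks, and 208, 146 and 108 in MRL/lpr replicates 1, 2 and 3 of 16 weeks. The sum of 152 in MRL/+ replicate 1 of 16 weeks was mostly Pvalb (131), which skeletal muscle also expresses. Those of 6 pituitary genes were 62.8, 85.6, 88.1 and 61.3 in MRL/lpr replicates 1, 2, 3 and 5 of 12 weeks and 62.9 in MRL/+ replicate 3 of 12 weeks, against a median of 31.6. Without the 4 libraries with the highest pineal, cerebellum and muscle sums, 34 genes were called at 12 weeks (28 higher and 6 lower), and camera called 25 lists in place of 24. Of 86 named genes that rose at 12 weeks, 10 kept their call in that fit, as did 6 of 12 that fell. That fit still holds libraries with cerebellum and pituitary transcripts.

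At 16 weeks MRL/lpr again held high levels of lymphoid transcripts. Cxcl13 was at 94.7 ± 63.0 CPM against 1.38 ± 0.71 (68.3-fold, log2 fold change 6.09, SE 0.76, adjusted p 0.00047), Jchain at 1144 ± 850.3 against 2.45 ± 1.09 (469-fold, 8.87, SE 1.06, adjusted p 0.00041), and Igkc at 4482 ± 3539 against 6.83 ± 1.6 (657-fold, adjusted p 0.00083). Ccl8 reached 252 ± 163 CPM against 0.336 ± 0.222 (757-fold, adjusted p 9.7e-05, and 1154-fold without MRL/+ replicate 2). Dmgdh stood at 21.5 ± 4.22 against 166 ± 19, 7.71-fold lower (-2.95, SE 0.14, adjusted p 2.4e-09). The test called 1410 genes higher and 439 lower, with median log2 fold changes of 3.32 and -0.59.

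The named lymphoid genes followed at 16 weeks. Ltb rose by 6.11 on the log2 scale (adjusted p 0.0019) and Cd4 by 5.26 (adjusted p 0.0025). Ms4a1, Cd3e, Cd8a and Pdcd1 had 3, 2, 1 and 2 counts over the MRL/+ libraries, and their count ratios were 175 (59.9 to 852), 145 (39.9 to 1199), 251 (44.8 to 9921) and 98.2 (27.0 to 813), with adjusted p 0.0030, 0.0025, 0.0016 and 0.0035. Ighm rose to 153 ± 152 CPM from 2.52 ± 0.603 (61.0-fold, adjusted p 0.0057, and 39.0-fold without MRL/lpr replicate 1), and Tnfsf13b 12.4-fold (adjusted p 0.0028). Cd68 rose to 18.7 ± 12.7 CPM from 2.9 ± 0.505 (adjusted p 0.015), and Cxcr5 had a count ratio of 145 (25.9 to 5748, adjusted p 0.012). Without MRL/+ replicates 1, 2 and 3, the adjusted p of Cd68 was 0.0637, 0.0608 and 0.0837 and that of Cxcr5 0.0534, 0.0615 and 0.0728. Ccl19 (count ratio 9.64, 3.16 to 48.0, adjusted p 0.078), Il21 (log2 fold change 0.65, adjusted p 0.13), Bcl6 (0.55, adjusted p 0.35) and Ttr (-0.44, adjusted p 0.17) did not pass.

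Of 10 tertiary lymphoid structure chemokines 8 rose at 16 weeks (10 adjusted over the list alone, median 6.86), with Cxcl9 at 167 ± 113 CPM against 0.285 ± 0.173. Of 15 lymphoid organisation genes 11 rose (13 adjusted over the list alone, median 6.09, or 4.05 with 4 genes at their bounds). Of 17 B cell genes 14 rose (17 adjusted over the list alone, median 6.40, or 5.85 with bounds). Of 12 plasma cell genes 9 rose (9 adjusted over the list alone, median 3.79). Of 12 immunoglobulin constant regions 11 rose (12 adjusted over the list alone, median 8.48). All 20 T cell genes rose (20 adjusted over the list alone, median 6.93, or 6.56 with bounds), and 11 of 14 cytotoxic and natural killer genes (13 adjusted over the list alone, median 5.62, or 5.13 with bounds). Of 18 macrophage genes 14 rose (15 adjusted over the list alone, median 2.75), with Adgre1, the antigen F4/80, up 7.64-fold (adjusted p 0.0016). Of 11 dendritic cell genes 8 rose (9 adjusted over the list alone, median 3.17). Of 10 microglia genes 6 rose (9 adjusted over the list alone, median 1.43), with Trem2, a lipid receptor of microglia and macrophages, up 5.44-fold (adjusted p 0.0018). Of 10 MHC class II genes 9 rose (10 adjusted over the list alone, median 5.02), as did all 12 MHC class I genes (12 adjusted over the list alone, median 3.03) and 16 of 18 interferon gamma response genes (17 adjusted over the list alone, median 5.18). Of 23 type I interferon response genes 22 rose (23 adjusted over the list alone, median 4.86), with Zbp1 up 139-fold (adjusted p 0.0014). Of 14 cytokines and inflammatory mediators 7 rose (11 adjusted over the list alone, median 1.92), with the macrophage growth factor Csf1 up 2.95-fold (adjusted p 0.0028). Of 13 leukocyte adhesion genes 11 rose (12 adjusted over the list alone, median 3.29, or 3.24 with bounds). Camera called these 16 lists with adjusted p 8.6e-14, 1.0e-10, 9.5e-13, 4.1e-09, 2.1e-16, 1.4e-25, 9.9e-13, 3.1e-13, 5.2e-08, 2.2e-07, 3.1e-11, 7.1e-12, 1.9e-18, 2.1e-17, 1.0e-05 and 7.6e-09, in the order given, each with adjusted p = 0.106 with an estimated correlation.

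Further immune lists passed at 16 weeks. Of 11 germinal centre and follicular helper T cell genes 7 rose (8 adjusted over the list alone, median 5.37, camera adjusted p 4.5e-07). Of 15 complement genes 10 rose (13 adjusted over the list alone, median 2.85, camera adjusted p 2.2e-09), with C4b up 10.2-fold (adjusted p 0.0028), and both had adjusted p = 0.107 with an estimated correlation. Of 18 proliferation genes 13 rose (14 adjusted over the list alone, median 2.14, camera adjusted p 7.7e-08, adjusted p = 0.172 with an estimated correlation), with Mki67, a marker of dividing cells, at 18 ± 15.6 CPM against 0.754 ± 0.366. Of 9 follicular dendritic cell genes 3 rose (3 adjusted over the list alone, median 0.18, camera adjusted p 0.0498, adjusted p = 0.41 with an estimated correlation). They were Cxcl13, which is also in the chemokine and lymphoid organisation lists, Fcgr2b and Madcam1. Fcgr2b did not pass in 2 and Madcam1 in 6 fits without 1 library. Their adjusted p reached 0.0607 without MRL/+ replicate 3 and 0.175 without MRL/+ replicate 1. Of 6 neutrophil genes 2 rose (2 adjusted over the list alone, median 0.75, camera adjusted p 0.015, adjusted p = 0.23 with an estimated correlation). These were again Lcn2 and Csf3r, each of which did not pass in 2 fits without 1 library. Their adjusted p reached 0.126 without MRL/+ replicate 3 and 0.0522 without MRL/+ replicate 2. As highest at 16 weeks the ranking rule took Ubd (at least 587-fold, adjusted p 0.0032) and the acute phase gene Saa3 (at least 284-fold, adjusted p 0.0063), both with 0 control counts and so of no firm rank. It also took the IgG constant regions Ighg1, Ighg2c, Ighg2b and Ighg3 (868-, 831-, 705- and 657-fold, adjusted p 0.0014, 0.0016, 0.0014 and 0.0016), Ccl8 and Igkc. The IgG regions are similar in sequence, so their counts may include each other's reads.

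In the tissue's own cells, the choroid plexus epithelium list was lower at 16 weeks (median -0.34, camera adjusted p 0.00012, adjusted p = 0.28 with an estimated correlation), and 3 of its 23 genes fell (5 adjusted over the list alone). They were the potassium channel subunit Kcne2 (chromosome 16, 92292389 to 92298129) at 613 ± 203 CPM against 1151 ± 32.8 (adjusted p 0.023), the prolactin receptor Prlr (log2 fold change -1.10, adjusted p 0.044) and the serotonin receptor Htr2c (-0.68, adjusted p 0.046). Kcne2 did not pass without MRL/+ replicates 1, 2 or 3 (adjusted p 0.0733, 0.0692 and 0.087). Prlr did not pass without MRL/lpr replicates 1, 2, 3, 4 or 6 (0.0932, 0.0824, 0.0776, 0.0525 and 0.0565) or MRL/+ replicates 1, 2 or 3 (0.114, 0.0701 and 0.181). Htr2c did not pass without MRL/lpr replicates 1, 2, 3 or 4 (0.106, 0.0882, 0.104 and 0.0793) or MRL/+ replicates 1, 2 or 3 (0.125, 0.0611 and 0.208). Of 13 epithelial junction genes 1 passed, Ocln (log2 fold change -0.53, adjusted p 0.036; 1 adjusted over the list alone; list median -0.10, camera adjusted p 0.33). Ocln did not pass without MRL/lpr replicates 1, 3 or 4 (0.090, 0.0857 and 0.0612) or MRL/+ replicates 1, 2 or 3 (0.0722, 0.0537 and 0.204). The heat shock list was lower (median -0.35, camera adjusted p 0.00015, adjusted p = 0.106 with an estimated correlation), with 3 of 9 genes falling (4 adjusted over the list alone), led by Dnajb1 (1.88-fold lower, adjusted p 0.00041). The others were Hspa1b (-1.48, adjusted p 0.024) and Hspa1a (-1.08, adjusted p 0.045), and Hsph1 stood at -0.18 (adjusted p 0.38). Hspa1b did not pass without MRL/lpr replicates 2 or 3 (0.0503 and 0.0576) or MRL/+ replicates 2 or 3 (0.0796 and 0.109). Hspa1a did not pass without MRL/lpr replicates 1, 2, 3, 4 or 6 (0.0504, 0.0606, 0.0672, 0.0851 and 0.0583) or MRL/+ replicates 1, 2 or 3 (0.0727, 0.123 and 0.169).

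Lists of other cells at 16 weeks had few called members. Astrocyte genes were higher by camera (11 genes, 0 passed, 0 adjusted over the list alone, median 1.58, adjusted p 0.0498, adjusted p = 0.57 with an estimated correlation), as were immediate early genes (12 genes, 1 rose, 3 adjusted over the list alone, median 0.80, adjusted p 0.0456, adjusted p = 0.50 with an estimated correlation). Not called were 14 endothelium genes (0 passed, 0 adjusted over the list alone, median 0.86, adjusted p 0.054), 14 neuron genes (1 rose, 1 adjusted over the list alone, median 1.44, adjusted p 0.14). Nor were 5 lymphatic vessel genes (1 rose, 1 adjusted over the list alone, median 0.79, adjusted p 0.18), 13 oligodendrocyte genes (0, 0 adjusted over the list alone, median 0.51, adjusted p 0.56) and 14 fibroblast and extracellular matrix genes (1 fell, 0 adjusted over the list alone, median -0.02, adjusted p 0.35). The 12 ependyma and cilia genes had a median of 0.08, while camera ranked the list downward (adjusted p 0.56; 0 passed, 0 adjusted over the list alone). The neuron gene that rose, Thy1, is also expressed by T cells (37.9 ± 17.3 CPM against 8.42 ± 4.81, adjusted p 0.030, and 0.0543 without MRL/lpr replicate 3 and 0.0614, 0.0835 and 0.14 without MRL/+ replicates 1, 2 and 3). The lowest folds by the ranking rule were those of Dmgdh, Bhmt2 (11.9 ± 3.19 CPM against 50.4 ± 5.11, 4.26-fold lower, adjusted p 5.7e-06), Mcoln3 (3.43-fold, adjusted p 0.0014). They also held Ins2 (chromosome 7, 142678656 to 142743381, a span that overlaps Igf2; 10.7 ± 4.07 CPM against 36.3 ± 3.28, 3.42-fold, adjusted p 0.0025), Tlx2 (3.29-fold, adjusted p 0.0028), Esrp1 (2.70-fold, adjusted p 0.0070), Emx1 and Rd3l. Emx1 (2.89-fold, adjusted p 0.010) did not pass without MRL/+ replicate 1 (0.0544), nor Rd3l (2.64-fold, adjusted p 0.030) without MRL/lpr replicates 1, 2 or 3 (0.0601, 0.0531 and 0.0564) or MRL/+ replicates 1, 2 or 3 (0.176, 0.0535 and 0.0775).

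At 16 weeks the test called 1849 genes (4773 at an unadjusted p under 0.05), and 775, 880 and 653 without MRL/+ replicates 1, 2 and 3. Scaling to the choroid plexus epithelium list moved the median of all genes from 0.025 to 0.41 and gave 3149 higher and 45 lower genes in place of 1410 and 439. Under it Kcne2, Htr2c and Ocln stood at -0.57, -0.32 and -0.15 and were not called (adjusted p 0.0629, 0.133 and 0.340), while Prlr stood at -0.78 and was (0.0325). Since Kcne2, Htr2c and Prlr belong to the list used for scaling, their move towards 0 is fixed by it and decides nothing. The 1410 higher genes were 680, 708 and 558 without MRL/+ replicates 1, 2 and 3. The 439 lower genes were 196, 255, 183, 223 and 880 without MRL/lpr replicates 1, 2, 3, 4 and 5, and 95, 172 and 95 without MRL/+ replicates 1, 2 and 3. With voom and sample weights 2401 genes were higher and 2448 lower. Without the 4 libraries with the highest pineal, cerebellum and muscle sums, 444 genes were higher and 54 lower, camera called 25 lists, as with all libraries, and 69 of 90 named genes that rose and 7 of 16 that fell kept their call.

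The strain differences at the 2 ages, which share no library, overlapped. Of the genes tested, 747 were higher in MRL/lpr at both ages, where 70.7 were expected for independent lists. Lower at both ages were 58, where 5.90 were expected, and 0 were called in opposite directions. Both comparisons come from 1 fit and share each gene's estimate of the spread, which favours the same genes at both ages. The expected numbers are therefore too low a reference. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.83 and a Spearman rho of 0.20. The 747 shared higher genes were 225, 315 and 270 without MRL/+ replicates 1, 2 and 3 of 12 weeks and 486 without MRL/+ replicate 3 of 16 weeks. The 58 shared lower genes were 22, 24 and 16 without MRL/+ replicates 1, 2 and 3 of 12 weeks, 26, 36 and 18 without those of 16 weeks, 37 without MRL/lpr replicate 1 of 12 weeks, and 33, 37 and 28 without MRL/lpr replicates 1, 2 and 3 of 16 weeks.

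**Figure D2:**
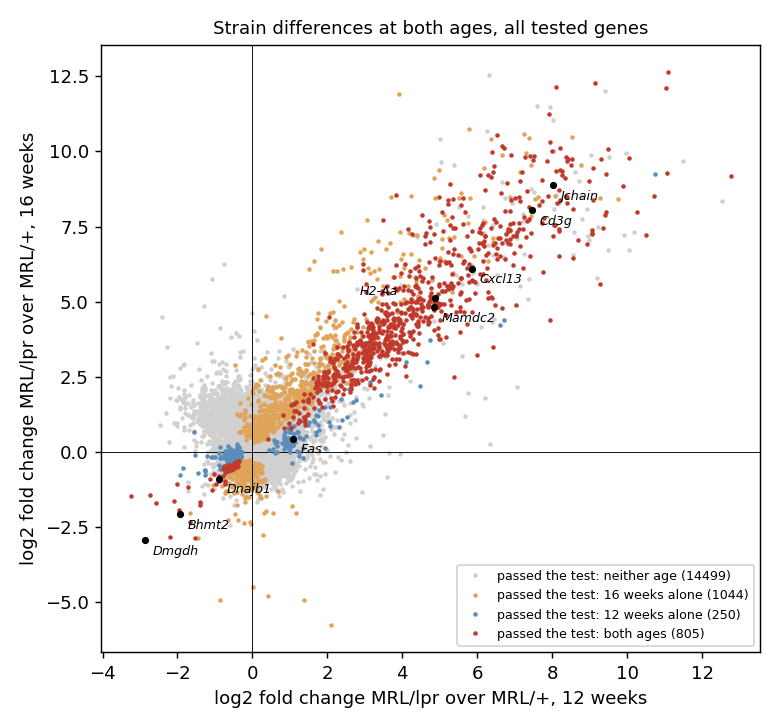
Log2 fold change of MRL/lpr over MRL/+ for each of 16598 genes at 12 weeks (horizontal) and 16 weeks (vertical), 1 point per gene, coloured by the ages at which the gene passed the test. The 805 genes called at both ages lie in the upper right and the lower left, 250 were called at 12 weeks alone, 1044 at 16 weeks alone and 14499 at neither.

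Rearranged antigen receptor genes were measured as well. Immunoglobulin genes together took 0.467 ± 0.297% of the counts in MRL/lpr at 12 weeks and 1.12 ± 0.869% at 16 weeks, against 0.00163 ± 0.000806% and 0.00157 ± 0.000334% in MRL/+. Of 136 immunoglobulin V segments tested, 41 rose at 12 weeks and 75 at 16 weeks. Of 10 T cell receptor V segments 9 and 10 rose. None of these segments fell.

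Between 12 and 16 weeks in MRL/lpr, edgeR called 6 genes, DESeq2 84 and voom with sample weights 21. The co-chaperone Hsph1 rose 1.92-fold, to 208 ± 36.9 CPM from 109 ± 11.6 (log2 fold change 0.94, SE 0.11, adjusted p 0.0041, n = 6 per age), and was called whichever 1 library was left out, but not in a fit of only the compared groups (adjusted p 0.0608) or without the 4 libraries with the highest pineal, cerebellum and muscle sums (0.157). Also higher at 16 weeks were Ahsa1, an activator of the chaperone HSP90 (77.0 ± 7.87 against 51.9 ± 5.23, adjusted p 0.024), and Dusp6, a phosphatase of ERK (28.3 ± 2.20 against 16.2 ± 2.82, adjusted p 0.040). Among the lower genes were the actin bundler Fscn2 (3.63 ± 0.652 against 7.53 ± 1.11, adjusted p 0.034) and the clock output gene Dbp (log2 fold change -1.44, adjusted p 0.040), which was singled out after its values were seen. Without 1 library the adjusted p of Ahsa1, Dusp6 and Fscn2 rose to as much as 0.0951 (MRL/lpr 12 weeks replicate 3), 0.152 (12 weeks replicate 4) and 0.119 (12 weeks replicate 4).

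By lists, the heat shock list was higher at 16 than at 12 weeks in MRL/lpr (median 0.43, camera adjusted p 1.7e-08, adjusted p = 0.060 with an estimated correlation, fry adjusted p 0.0025), with 1 of 9 genes rising (5 adjusted over the list alone). None of 23 type I interferon response genes rose over all genes (8 adjusted over the list alone, median 1.70, camera adjusted p 7.5e-07). Oas1a, Ifit3 and Mx1, antiviral proteins induced by interferon, stood at 12.8 ± 18.1, 63.7 ± 104 and 8.76 ± 15.1 CPM at 16 weeks against 3.18 ± 2.0, 14.2 ± 7.82 and 2.01 ± 0.983 at 12 weeks, with an SD above the mean at 16 weeks. Camera also called as higher the plasma cell (median 0.71, adjusted p 0.011), T cell (0.53, 0.011), cytotoxic and natural killer (0.50, 0.031), interferon gamma (0.56, 0.031), MHC class I (0.44, 0.034), macrophage (0.35, 0.041), neutrophil (0.53, 0.041), microglia (0.32, 0.034) and neuron lists (0.80, 0.034). It called as lower the fibroblast and extracellular matrix (-0.30, 0.0014), ependyma and cilia (-0.40, 0.034) and oligodendrocyte lists (-0.31, 0.031). Each of these 13 lists other than heat shock had adjusted p = 0.83 with an estimated correlation, and 0 of their members passed over all genes. The lymphatic vessel list had a median of 0.02, while camera ranked it downward (adjusted p 0.99). The 14 lists called by camera depend on single libraries: they were 22, 7, 6 and 6 without MRL/lpr replicates 1, 3, 4 and 5 of 12 weeks, and 2, 3, 5, 6 and 24 without replicates 1, 2, 3, 4 and 6 of 16 weeks. Scaled to the epithelium list 6 lists were called, and fry called 1.

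The 6 genes were 3 in each direction (1117 at an unadjusted p under 0.05). The count was 1 with the replicate number as a block and 0 in a fit of only the compared groups, and 1, 2, 1 and 3 without MRL/lpr replicates 2, 3, 4 and 5 of 12 weeks and 3, 2 and 1 without replicates 1, 4 and 5 of 16 weeks. Scaling to the choroid plexus epithelium list moved the median of all genes from 0.017 to 0.12 and left 1 gene. Without the 4 libraries with the highest pineal, cerebellum and muscle sums 0 genes were called.

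Between 12 and 16 weeks in MRL/+, with 3 libraries per age, edgeR called 0 genes (2173 at an unadjusted p under 0.05, smallest adjusted p 0.107), DESeq2 12 and voom with sample weights 1724. Camera called 0 lists. The medians of the astrocyte and immediate early gene lists were -1.22 and -0.80 (camera adjusted p 0.147 for both), and the median of the neuron list was -1.20 (adjusted p 0.39). MRL/+ replicate 1 of 12 weeks, which had the highest sum of cerebellum genes, was among the younger libraries. The germinal centre, cytotoxic and cytokine lists had medians of -0.13, -0.09 and -0.37, while camera ranked them upward (adjusted p 0.91, 0.91 and 0.96). Ccl8 stood at 0.336 ± 0.222 CPM at 16 weeks and 0.32 ± 0.204 at 12 weeks.

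The strain by age interaction, which tests whether the strain difference itself differs between the ages, was called for 0 genes by edgeR (2286 at an unadjusted p under 0.05, smallest adjusted p 0.361), and for 0 by DESeq2 and by voom. Genes called at 16 weeks alone are therefore not shown to differ between the ages. Camera called 1 list, fibroblasts and extracellular matrix (14 genes, 0 passed, 0 adjusted over the list alone, median -0.73, adjusted p 0.0072, adjusted p = 0.998 with an estimated correlation). It did not pass without MRL/lpr replicate 6 of 12 weeks (adjusted p 0.124) or with the neuron score as a covariate (0.0595), fry called 0 lists, and its median was -0.36 without MRL/+ replicate 1 of 16 weeks. The proteoglycan genes Dcn and Lum of this list had interaction values of -0.76 (SE 0.30) and -0.91 (SE 0.40), with adjusted p 0.361 for both. The type I interferon response list had a median of 1.39 (camera adjusted p 0.052). The medians of the B cell, MHC class II and proliferation lists were 0.34, 0.16 and 0.24 while camera ranked them downward (adjusted p 0.99, 0.89 and 0.82), and those of the follicular dendritic cell and neutrophil lists were -0.02 and -0.80 while it ranked them upward (0.89 and 0.97). Scaling to the epithelium list moved the median of all genes from 0.079 to 0.22.

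Scores of whole lists separated the strains library by library. The score of the tertiary lymphoid structure chemokines was 1.48 ± 0.83 in MRL/lpr and -3.38 ± 0.191 in MRL/+ at 12 weeks, and 1.88 ± 1.23 and -3.34 ± 0.522 at 16 weeks. The B cell score was 1.14 ± 0.973 and -2.45 ± 0.135 at 12 weeks and 1.29 ± 1.5 and -2.40 ± 0.115 at 16 weeks, and the T cell score 1.31 ± 0.892 and -3.05 ± 0.105, and 1.78 ± 1.3 and -3.13 ± 0.00793. For these 3 lists every MRL/lpr library was above every MRL/+ library of its age. The exact permutation p was 0.0119, the smallest possible with 84 splits (0.0159 adjusted over the 4 lists at both ages together). The epithelium score was lower in MRL/lpr by an amount that did not pass after adjustment, -0.0608 ± 0.133 against 0.192 ± 0.155 at 12 weeks (exact permutation p 0.048, adjusted 0.054) and -0.149 ± 0.262 against 0.227 ± 0.196 at 16 weeks (exact permutation p 0.071, adjusted 0.071).

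**Figure D3:**
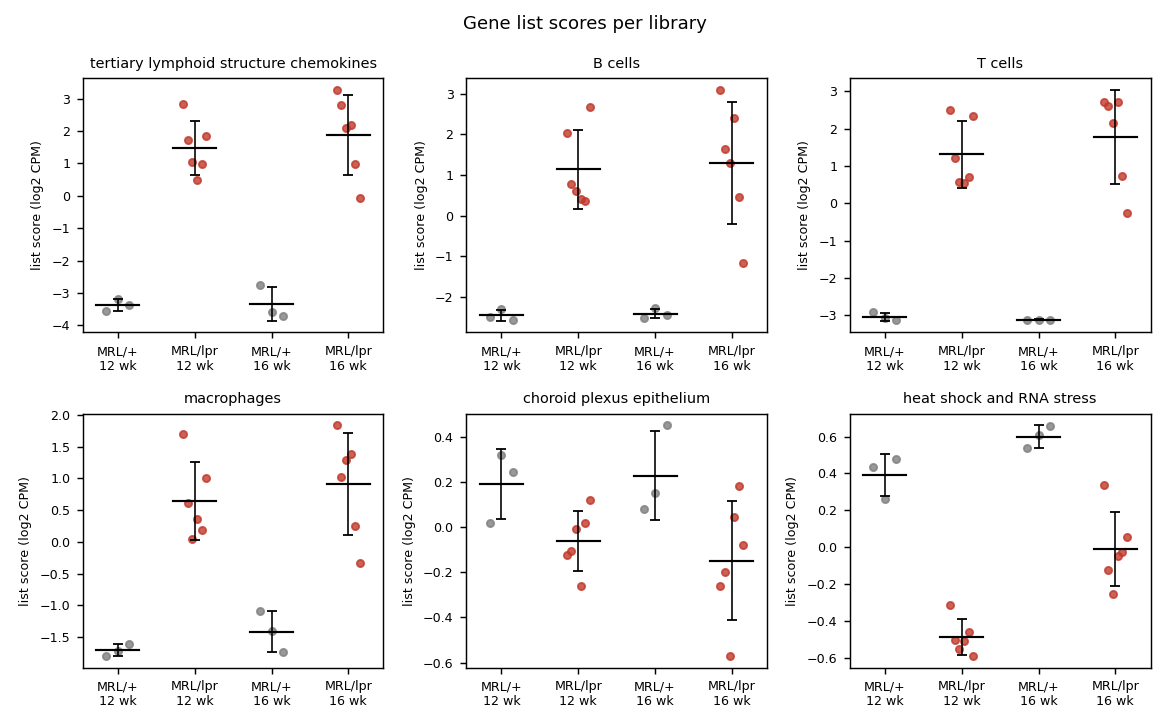
Scores of 6 gene lists (mean centred log2 CPM of the list's genes) in each library, with MRL/+ in grey, MRL/lpr in red, 1 point per library, and black lines and bars at the mean ± SD. MRL/lpr libraries lie above the MRL/+ libraries of their age for the chemokine, B cell, T cell and macrophage lists and below them for heat shock, and the strains overlap for the epithelium list.

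Within the 6 MRL/lpr libraries of an age, 6 relations between scores were computed and adjusted together. At 16 weeks the B cell and T cell scores rose together (Pearson r 0.944, exact permutation p 0.00139, adjusted 0.00833; Spearman rho 1, p 0.00278, adjusted 0.0167; r 0.917 without the 2 libraries farthest from the median B cell score). The B cell and chemokine scores had r 0.942 (exact permutation p 0.00694, adjusted 0.0208) and rho 0.943 (p 0.0167, adjusted 0.050), with r 0.719 without the 2 farthest libraries. At 12 weeks the B cell and T cell scores had r 0.947 (exact permutation p 0.0194, adjusted 0.0389) and rho 0.771 (p 0.103, adjusted 0.154), with r 0.732 without the 2 farthest libraries. The B cell and chemokine scores at 12 weeks had r 0.756 (exact permutation p 0.079, adjusted 0.119) and rho 0.886 (p 0.033, adjusted 0.067), with r 0.836 without the 2 farthest libraries. The B cell and epithelium scores had r 0.460 (exact permutation p 0.371, adjusted 0.445) and rho 0.200 at 12 weeks (p 0.714, adjusted 0.714), with r 0.0674 without the 2 farthest libraries, and r -0.225 (p 0.672, adjusted 0.672) and rho -0.314 (p 0.564, adjusted 0.677) at 16 weeks, with r -0.103 without them.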

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

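Chosen after the result was seen were the tests of the lower genes, the heat shock genes and the clock genes. Spreads given below with medians and their differences are SDs over resampled genes, so they leave out the variation between libraries. Among 102 groups of values of 6 libraries, 1 library lay far from the others, where chance alone gives about 1 in 20, or 5.1. It was MRL/lpr replicate 4 of 16 weeks, whose endothelium score was 1.57, with the other 5 libraries of the group between -0.35 and 0.07. A single such library is within what chance gives.

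The fibroblast and extracellular matrix list differed between the ages in its strain difference (median interaction -0.73, camera adjusted p 0.00715). The strain difference of this list was 0.44 at 12 weeks and -0.02 at 16 weeks. With the correlation between genes estimated from the data the adjusted p was 0.998, with the neuron score as a covariate 0.0595, and without MRL/lpr replicate 6 of 12 weeks 0.124, and fry called 0 lists. Without MRL/+ replicate 1 of 16 weeks the median was -0.36 (adjusted p 0.0228). The result therefore depends on the test, on that covariate and on single libraries.

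Splits of the same libraries into other groups compare the number of called genes with that of other groupings. They treat the libraries as exchangeable, although the labels do not say that these are separate animals. For the strain difference at 12 weeks, the real grouping called 1055 genes and was the 1 of 84 splits to reach that number, with at most 10 in the others. A share of 1 in 84 is the smallest that these splits allow, which makes chance unlikely but does not exclude it. At 16 weeks the real grouping called 1849 genes and was again the 1 of 84 splits to reach its number, the same smallest share. The highest other split there called 568 and set MRL/lpr replicates 1, 3 and 4 against the other 3 MRL/lpr and the 3 MRL/+ libraries, so it holds part of the strain difference. For age in MRL/lpr, 2 of 100 splits drawn from 462, the real one included, called at least as many genes as the real one. That share is under 0.05, but the real value was only 6 and another grouping called 12, so chance is not excluded. For age in MRL/+, 10 splits are too few for a share under 0.05 (10 of 10 reached the real value of 0, highest other 0). For the interaction, any split reaches the real value of 0 (100 of 100, highest other 1), so the splits decide nothing there and chance is not excluded.

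At 16 weeks 439 genes were lower in MRL/lpr, and 394 of them were no longer called once the libraries were scaled to the epithelium list. At 12 weeks, in other libraries, the median of the 394 was 0.053 after scaling (spread 0.013), but they lay as far below the median of all genes after scaling as before it (-0.19 both times), so dilution by RNA of infiltrating cells cannot be told apart for them. Of the 45 still called, 12 were over 3 times higher in MRL/+ replicate 1, where 6 skeletal muscle genes that are not among the 12 summed to 388 CPM against at most 1.75 elsewhere, so muscle RNA is a candidate source. The other 33 had a median of -0.45 after scaling at 12 weeks (spread 0.142), in libraries that share nothing with the muscle library. Of these, 27 were below 0 there and 11 were called lower. This argues against dilution and muscle RNA as the whole cause for the 33 as a set, but not for each gene. For these 33 a difference between the strains stays open, as untested.

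The 9 genes of the heat shock list were lower in MRL/lpr at both ages (medians -0.46 and -0.35). After scaling to the epithelium list the medians were -0.20 at 12 weeks and 0.023 at 16 weeks, with 8 and 4 genes lower. For the list as a whole, dilution is therefore not argued against. The 4 genes called at 12 weeks had, at 16 weeks in other libraries, a median of -0.998 as fitted and -0.58 after scaling (spread 0.285). Dnajb1 was still called after scaling (log2 fold change -0.62 and -0.53, adjusted p 0.0195 and 0.0245). For these 4 as a set, dilution is argued against as the whole cause, but not for each gene. The set is small, Hspa1a and Hspa1b are near-identical, and the spread was resampled over the same 4 genes. Hsph1 was at -0.18 as fitted at 16 weeks, so for Hsph1 dilution is not argued against. For the other 5 genes dilution cannot be told apart, with medians of -0.075 at 12 weeks and 0.074 at 16 weeks after scaling (spread 0.117 and 0.135), since the scaling moves all genes alike. Neurons in the dissection are argued against as the cause. The neuron score as a covariate moved the 9 genes towards 0 by a median of at most 0.038 (spread 0.034). That score differed between the strains in opposite directions at the 2 ages (-0.49 and 0.84), as did the astrocyte score (-0.21 and 1.05). The oligodendrocyte (0.46 and 0.32) and ependyma scores (0.53 and 0.16) were higher in MRL/lpr at both ages, though neither difference passed. Brain tissue with few neurons therefore cannot be told apart. Collection of the strains at another time of day cannot be told apart, since the clock output genes moved both ways (median strain differences -0.071 and -0.13, with 5 and 4 of 8 lower). Of single genes, Hlf, an output gene, was lower at both ages (log2 fold change -1.14 and -0.92, adjusted p 0.017 and 0.038), and so was Clock (-0.62 and -0.59, adjusted p 0.048 and 0.044), an antiphase gene that a shift in time would move the other way; a difference in handling, or between the strains, stays open and untested.

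Of 13 clock genes, in lists written after Dbp was seen, Dbp alone passed with age in MRL/lpr (log2 fold change -1.44, adjusted p 0.040), and none passed in MRL/+ (smallest adjusted p 0.379). As groups, the median of the antiphase genes minus that of the output genes other than Dbp was 0.88 in MRL/lpr (spread 0.34) and 0.91 in MRL/+ (spread 0.273) between 16 and 12 weeks. Collection at another time of day at the 2 ages is therefore a candidate explanation, though the MRL/lpr libraries of 16 weeks were uneven. In replicates 1, 5 and 6 the output scores, Dbp included, were -0.60, -1.02 and -0.51 and the antiphase scores 0.24, 0.67 and 0.63. Replicates 2, 3 and 4 had output scores of 0.10, -0.0036 and -0.22 and antiphase scores of -0.38, -0.14 and -0.032. A shift shared by all libraries of that age is not shown. Neurons in the dissection are argued against as the cause, since the smaller difference was 0.89 with the neuron score as a covariate (spread 0.298). Brain tissue with few neurons was not tested. An effect of age itself stays open, as untested.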

How the results depend on the processing

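The neuron score covariate, the scaling to the epithelium list and the fit without 4 libraries were chosen after the data were seen. In the simulated data the strain comparisons recovered 44% and 34% of 2-fold changes, so most changes of that size were missed. Whether low counts or the 3 control libraries set this limit was not tested. Not every called result kept its sign. The median of the heat shock list at 16 weeks was -0.35 as fitted and 0.023 when scaled to the epithelium list. With voom more genes were lower than higher at both ages. The called lists at 12 weeks (24 to 26) and 16 weeks (22 to 25) stayed within 1.5 times of their number when any 1 library was left out. Of 209 calls of named genes, DESeq2 kept 209, RLE 208, voom 201, the covariate 205, scaling to the epithelium list 196, no filter 195, only the compared groups 191 and the fit without 4 libraries 92 (10 of 86 that rose at 12 weeks, 69 of 90 at 16 weeks). The cause of the changes below was not tested, except that fewer libraries or other genes tested change the power by construction.

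With DESeq2, 1665 genes changed at 12 weeks (1336 higher), 84 with age in MRL/lpr and 12 with age in MRL/+. With voom and sample weights, 3490 changed at 12 weeks (1580 higher, 1910 lower), 4849 at 16 weeks (2401 higher, 2448 lower), 21 with age in MRL/lpr, 1724 with age in MRL/+, and 517 were lower at both ages. With RLE, 130 were lower at 12 weeks and 38 at both ages, and 3 lists were called for the interaction. Calls of at least 1.5-fold left 91 lower genes at 12 weeks and 223 at 16 weeks. With no low-count filter 61 were lower at 12 weeks, 171 at 16 weeks and 19 at both, and the overlap r was 0.51. With at least 1 CPM in at least 6 libraries 137 were lower at 12 weeks and 36 at both. With only the compared groups 85 were lower at 12 weeks, 291 at 16 weeks, 0 changed with age in MRL/lpr, and 20 were lower at both ages with each age fitted alone.

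Scaled to the epithelium list, 21 genes were lower at 12 weeks, 3194 changed at 16 weeks (3149 higher, 45 lower), 1 changed with age in MRL/lpr, 11 were lower at both ages, and 6 lists were called with age in MRL/lpr. With the neuron score as a covariate 506 were lower at 12 weeks and 0 lists were called for the interaction. Leaving out the 4 libraries with the highest pineal, cerebellum and muscle sums, 34 changed at 12 weeks (28 higher, 6 lower), 498 at 16 weeks (444 higher, 54 lower) and 0 with age in MRL/lpr, 27 were higher and 5 lower at both ages, and 7 lists were called for the interaction. With the estimated correlation 0 lists were called at 12 weeks, at 16 weeks, with age in MRL/lpr and for the interaction. Fry called 23 lists at 12 weeks, 24 at 16 weeks, 1 with age in MRL/lpr and 0 for the interaction. Of lists called by camera, it did not call epithelium and epithelial junctions at 12 weeks (fry adjusted p 0.15 and 0.061). At 16 weeks it did not call astrocytes and immediate early genes (fry adjusted p 0.20 and 0.14). It did call follicular dendritic cells at 12 weeks (0.045) and lymphatic vessels at 16 weeks (0.038), which camera did not. The median over the list gave an epithelium score difference of -0.22 at 12 weeks (exact permutation p 0.107).

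With the replicate number as a block, 212 genes were lower at 16 weeks, 1 changed with age in MRL/lpr, and 4 lists were called for the interaction. The numbers gave no sign of pairing, since 6 of 21 pairs of the same number had a correlation over 0.1 (range -0.62 to 0.45).

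Leaving out each library in turn, the genes changed at 12 weeks ranged from 263 to 1477 (higher 229 to 969, lower 34 to 508), at 16 weeks from 653 to 2600 (higher 558 to 1720, lower 95 to 880) and with age in MRL/lpr from 1 to 9. Genes higher at both ages ranged from 225 to 782 and lower at both from 16 to 65. Lists called ranged from 2 to 24 with age in MRL/lpr, 0 to 2 with age in MRL/+ and 0 to 5 for the interaction. The epithelium score difference ranged from -0.34 to -0.19 at 12 weeks and -0.45 to -0.26 at 16 weeks. The r of B and T cell scores at 12 weeks ranged from 0.938 to 0.975, and that of B cell and chemokine scores from 0.716 to 0.948 at 12 weeks and 0.848 to 0.975 at 16 weeks. The lowest gene counts of the strain comparisons came without an MRL/+ library (replicate 1 of 12 weeks, 263, and replicate 3 of 16 weeks, 653).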

Other observations

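The test of neighbouring genes was chosen after the result was seen. Some strain differences were large and even across libraries. Mamdc2 (chromosome 19, 23302609 to 23448322) was at 37.7 ± 7.16 CPM in MRL/lpr and 1.28 ± 0.518 in MRL/+ at 12 weeks (log2 fold change 4.85, adjusted p 1.0e-08), and at 41.7 ± 5.08 and 1.46 ± 0.424 at 16 weeks (4.81, adjusted p 1.2e-08). The histone methyltransferase Ezh1 (chromosome 11, 101191115 to 101226463) was at 49.1 ± 6.11 and 15 ± 3.83 at 12 weeks (1.70, adjusted p 0.00012), and at 53.7 ± 8.94 and 11.7 ± 2.13 at 16 weeks (2.20, adjusted p 6.0e-06). Both were singled out after their values were seen.

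With the leukocyte score as a covariate, 39 genes differed between the strains at both ages, 19 higher and 20 lower in MRL/lpr. Among them were Mamdc2 (4.41 and 4.35, adjusted p 5.8e-06 and 7.4e-06) and Dmgdh (-2.76 and -2.84, adjusted p 0.00023 and 0.00024). The leukocyte scores of the strains did not overlap (-2.43 to -2.24 in MRL/+ and -0.59 to 2.55 in MRL/lpr), so the covariate extrapolates and does not separate strain from leukocyte content. One hypothesis is that the strains differ in stretches of the genome beside the lpr allele, which could place such genes side by side. There were 5 pairs of these genes within 1 Mb, against a median of 1 in 10000 random sets of as many genes (at most 7, p 0.01). The pairs were Drc1 with Emilin1, Trbc1 with Trbc2, and the 3 among Cyb561a3, Ms4a4b and Gm8369. The last 3 genes form 1 cluster on chromosome 19, which lies over 20 Mb from Fas. Mamdc2 is on the same chromosome, within 20 Mb of Fas. Without Trbc1, Trbc2 and Ms4a4b, which T cells express, 2 pairs were left (p 0.269 against random sets), so a shared stretch and cell content cannot be told apart. Of genes within 20 Mb of Fas, 1 of 252, Mamdc2, was among the 39 (odds ratio 1.71, 95% interval 0.042 to 10.2, Fisher's exact p 0.45), too few to decide whether genes flanking Fas are enriched.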
